A study of Drosophila melanogaster with 3 samples.

How the data were processed

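Per the labels, chromatin was taken from whole Drosophila melanogaster embryos of both sexes, 0 to 24 hours after egg laying, of a fly line with a stable transgene in which chiffon (chif) is fused to eGFP. The fused protein and the DNA bound to it were recovered with an antibody against GFP, after sonication to fragments of 200 to 800 bp, and the DNA was sequenced. The 3 samples formed 1 group of 3 biological replicates, labelled as separate biosamples of the same strain. The name of that strain carries the transcript chif-RB in all 3 labels, and the note on the fusion, which places GFP at the C-terminus, names chif-RB for replicate 1 and chif without a transcript for replicates 2 and 3. Which of the protein products of chif carry the tag was not worked out here. There was thus no comparison between groups, and the p-values below compare regions or genes within these embryos. No labels paired the replicates with anything else.

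The authors deposited peak lists in the narrowPeak form, on the genome builds dm6 and dm3. Per the file headers and the notes deposited with the samples, 1 list per replicate was called from that replicate's own alignments and 1 list from the alignments of the 3 replicates pooled, in each case against the same 1 control file per build. A further thresholded list was derived by the authors from these lists with the irreproducible discovery rate, a measure of how well ranks repeat between replicates. Peaks were thus called both per replicate and on pooled reads. The aligner, the peak caller and their settings are not given in the sources used here. Each region has a signal that the authors' caller gave it, a −log10 of a q-value deposited beside it, and the offset of its summit from its start in bp. The signal is the authors' own score per region and was used here to describe, rank and filter regions within a list, never to compare lists. The −log10 values were not used for ranking, because they reach a ceiling at the top of each list. Each replicate list and the pooled list held exactly 30000 regions, so their length is a fixed maximum and not a measure of how much was bound. The 5035 thresholded regions on dm6 were, line for line, the 5035 pooled regions of highest signal, and the 4680 on dm3 were likewise the highest of that pooled list. The lists hold no read counts, so the depth of each sample is unknown, and no interval that needs it is given. Signal tracks and the control libraries were not used here.

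Coordinates are 1-based and on dm6. Genes, transcripts and sequence came from the BDGP6.54 copy of the same Release 6 assembly with its Ensembl annotation, release 115, whose chromosome names and lengths the dm6 regions fit. No dm3 sequence was used here, and random placements on dm3 took the end of the last region on each arm as its length. All dm6 regions lay on the arms 2L, 2R, 3L, 3R, 4, X and Y, with 1 on Y, in the list of replicate 2. A transcription start site (TSS) is the 5' end of any annotated transcript. There were 24111 such positions, of which 19630 belonged to protein-coding genes. A protein-coding gene was called bound when a summit lay within 500 bp of any of its TSSs.

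For agreement between replicates, the 5035 regions of highest signal were taken from each replicate, here called its top regions. The share of one replicate's top regions whose summit lay inside a top region of another was compared with 1000 random placements on the same arm by a one-sided permutation test. A summit inside the region was the minimum overlap throughout. For position relative to genes, each summit was given the first class that applied out of promoter (within 500 bp of any TSS), 5' UTR, coding exon, 3' UTR, noncoding exon, intron and intergenic. Shares were compared with 1000 random placements on the same arm by a two-sided permutation test, with Benjamini-Hochberg adjustment over the 7 classes. The noncoding exon class was added once the annotation had been read. Gene lists and arms were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 14 lists or the 7 arms, Y included. All 527 listed symbols were found in the annotation, 3 of them under an older symbol. The lists were replication licensing and firing, replication fork and nucleotide supply, cell cycle regulators, SAGA and Gcn5 acetyltransferase subunits, chorion genes, cytoplasmic ribosomal proteins, chemosensory receptors, segmentation and homeotic genes, heat shock genes, architectural and promoter-binding proteins, and markers of neural cells, of mesoderm and muscle, of the germ line, and of blood and fat body.

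For sequence, windows of 100 bp to either side of each promoter summit were searched on both strands for 13 motifs and for all 6-mers. They were compared with windows of the same width around the TSSs of protein-coding genes that had no thresholded region within 2000 bp, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the motifs or over the 6-mers. An adjusted p under 0.05 was called past the threshold. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only.

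The samples' grouping, the tests, the gene lists, the motifs and a first set of alternatives were fixed before the data were examined. So was the rule for the genes that are named. It takes the protein-coding genes with a TSS within 500 bp of the 15 highest-signal thresholded regions that hold a top summit of each replicate, chif itself, and from each gene list up to 3 bound members of highest signal and up to 2 unbound members, first by alphabet. A gene named outside this rule was chosen after its values were seen. These alternatives were TSS distances of 250 and 1000 bp, the higher-signal part of the thresholded list (2517 regions), leaving out each replicate, regions held by each of the 3 replicates, and a list built here from top regions backed by at least 1 other replicate. They further covered K of 1000 and 10000 top regions, reciprocal overlap of 50%, summits within 100 bp, the dm3 lists, random placements within 10 kb, circular shifts of all regions, genes with no other TSS within 1000 bp, windows of 50 bp, and background windows 1000 bp to either side. Where a replicate was left out, a thresholded region had to hold a top summit of both other replicates. The region, its summit and its signal still came from the pooled reads, which include those of the replicate left out. The demand for 2 top summits asks more than the authors' list does. Alternatives added after seeing the data were random placements matched on GC content in steps of 2.5 points, a list from replicates 1 and 3 without reads of replicate 2, the top regions of each replicate by itself, and background windows moved off the unbound TSSs by distances drawn from those of the promoter summits (seeded draw). Also added then were the alternatives of the 6-mers other than the windows to either side, those of the median distance to the TSS, and leaving out a replicate from the agreement. So were the position classes other than promoter among summits outside promoters, against placements outside promoters, also within 10 kb, with GC matching and per replicate, with Benjamini-Hochberg adjustment over 6 classes. The same holds for 4 further gene lists, with their alternatives and with the members that led to their choice left out.

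The scripts were tested on simulated data first. Of the 7 position classes, 0 were called on random regions, and planted promoter regions were recovered at their planted share of 48.0%, with 0 of 6 classes called among the simulated regions outside promoters. Of 100 random gene lists, 5 passed before adjustment. The simulation drew the bound state of each gene separately, so it does not cover neighbouring genes that share a region. Lists planted with an odds ratio of 4 passed, also before adjustment, in 90 of 100 draws at 20 members, in 99 at 30 members and in 100 at 86 members. Smaller odds ratios were not simulated, and the real lists were judged after adjustment. A planted motif was found, with 0 of 11 others called. All computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.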

Results

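The data list regions recovered with an antibody against GFP from fly embryos that carry a GFP-tagged chiffon protein. Below, chif-eGFP is said to bind or to lie where such a region was listed. An untagged library was not analysed here, so general recovery of promoters is not separated from binding of chiffon. Chiffon is the fly relative of Dbf4, the partner that activates the Cdc7 kinase at replication origins, and another part of its product has been tied to the histone acetyltransferase Gcn5. The 3 biological replicates of 1 group, mixed-sex embryos 0 to 24 hours old, each gave a list of 30000 regions, as did their pooled reads, and the authors' thresholded list held 5035 regions. Thresholded regions had a median width of 410 bp (range 102 to 608 bp), and the authors' signal ran from 106 to 3635 with a median of 179. Median widths in replicates 1, 2 and 3 were 410, 370 and 400 bp. The depth of the libraries is unknown, and 1 control file served all lists of a build.

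The strongest chif-eGFP regions returned in each replicate, and replicates 1 and 3 shared more of them with each other than either did with replicate 2. Of the 5035 top regions, replicates 1 and 3 shared 79.6%, replicates 2 and 3 shared 63.4% and replicates 1 and 2 shared 61.0%. The mean over the pairs was 68.0% ± 10.1 (SD, n = 3 pairs), against 1.37% for regions placed at random on the same arms (one-sided permutation test, p = 0.001 for each direction of each pair, the smallest the placements can give). Among the thresholded regions, 2815 (55.9%) held a top summit of all 3 replicates, 1587 (31.5%) of exactly 2, 603 (11.98%) of 1 and 30 (0.596%) of none. Replicate 2 backed 69.5% of them, replicate 1 84.9% and replicate 3 88.4%. The shared control is a limit here, because random placement does not model places that the control would raise in every list. Placement over the whole arm also ignores that summits gather at promoters, so these p-values set a low bar. The thresholded list comes from the pooled reads of the same 3 replicates, so their backing of it is not independent.

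The 15 strongest thresholded regions lay within the first 17, 26 and 20 regions of replicates 1, 2 and 3. Of these regions, 10 had a protein-coding TSS within 500 bp, and 14 genes were assigned to them. The second strongest region, at 2R:22514083–22514521 with a signal of 3594, had its summit in an intron of px (FBgn0003175, 2R:22494297–22562065), a gene of wing vein patterning, 205 bp upstream of an internal TSS. The next, at 3L:19590404–19590827 with a signal of 3349, was intergenic and 96 bp upstream of CG14100 (FBgn0036889, 3L:19589072–19590524). At ph-p (FBgn0004861, X:2126210–2138371), which encodes a subunit of Polycomb repressive complex 1, the summit lay at X:2137343 in an intron with a signal of 2894, 488 bp upstream of a TSS. With a TSS distance of 250 bp the ph-p region would be another one, of signal 161. A region at 3L:22878697–22879130, signal 2867, had its summit in the 5' UTR of Chro (FBgn0044324), 101 bp downstream of its TSS and 206 bp upstream of that of Ssl1 (FBgn0037202), which runs the other way. Chro encodes the interband and spindle protein Chromator and Ssl1 a subunit of the general transcription factor TFIIH.

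The intergenic summit at 3R:15229521, signal 2594, lay 113 bp upstream of the arginine methyltransferase gene Art3 (FBgn0038306) and 144 bp upstream of mRpS10 (FBgn0038307), which encodes a mitochondrial ribosomal protein. The intergenic summit at 2L:13835468, signal 2151, lay 96 bp upstream of CenG1A (FBgn0028509) and 396 bp upstream of mRpS23 (FBgn0260407), another gene of the mitochondrial ribosome. Another such summit at 3L:5139508, signal 2231, lay between CHMP2B (FBgn0035589), a gene of the membrane-severing ESCRT-III complex, and Tcs5 (FBgn0035590), 111 and 113 bp upstream of them. Single genes with a strong region were Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, with an intergenic summit 30 bp upstream and a signal of 2772, CG1888 (FBgn0033421), with a 5' UTR summit and a signal of 2287, and PNPase (FBgn0039846), a mitochondrial exoribonuclease gene, with an intronic summit 78 bp upstream of a TSS and a signal of 2199.

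The other 5 of the strongest regions had no protein-coding TSS within 500 bp. The strongest region of the list, at 2L:480841–481332 with a signal of 3635, lay in an intron of ush (FBgn0003963), which encodes a partner of GATA factors, and 1370 bp from the nearest TSS, that of cbt. Regions in introns of CG11050 (2L:6612504–6612923, signal 2606) and of the kinase gene Lk6 (3R:11760855–11761250, signal 2418) lay 1038 and 967 bp from a TSS. The last, at 2R:13035129–13035539 with a signal of 1822, was intergenic and 11910 bp from the nearest TSS. The tenth was at chif itself.

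The chif gene (FBgn0000307, 2L:16342430–16352628, minus strand) had 2 thresholded regions inside it and 1 just upstream. The strongest, at 2L:16351022–16351473 with its summit at 16351266 and a signal of 2357, ranked 10 in the whole list and lay in the first intron of the longer transcripts, 983 bp from the nearest chif TSS. Hyls1 is annotated over the same span and strand. A second region had its summit at 16350367, in the same intron and 84 bp upstream of an internal chif TSS at 16350283, with a signal of 353 and rank 845. The third summit, at 16352754, was intergenic, with a signal of 133 and rank 3733. It lay 126 bp upstream of the outer TSS, which chif shares with Hyls1, and 180 bp from the TSS of the divergent gene CG4455, so it counts for these genes as well. At 500 bp the second and the third of these each make chif a bound gene, and the second, of higher signal, is the one given for it. At 1000 bp the strongest one, signal 2357, counts as well. Chif is also the tagged transgene, and reads of the transgene and of the gene itself cannot be separated in a peak list.

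**Figure D1:**
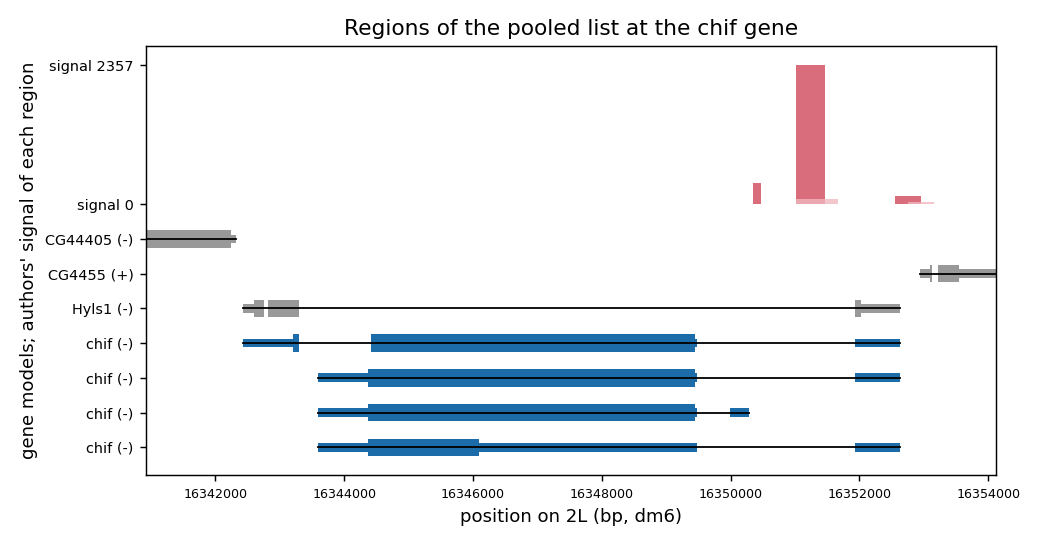
Regions of the pooled list at the chif gene, with position on 2L (bp, dm6) on the horizontal axis and the authors' signal of each region as the height of its bar (dark: thresholded, pale: not thresholded), above the annotated transcripts (thick: coding, thin: untranslated or intron). The strongest region, signal 2357, lies in the first intron, between a weaker region near the internal TSS, signal 353, and one upstream of the outer TSS, signal 133.

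In the thresholded list chif-eGFP lay mainly at promoters and introns and was nearly missing from coding sequence. Of the 5035 thresholded summits, 2388 (47.4%, 95% interval 46.0 to 48.8%) lay within 500 bp of a TSS, against 13.6% of random placements. Coding exons held 14 summits (0.278%, 0.152 to 0.466%), against 13.7% of random placements, and 3' UTRs 0.814% against 4.44%. The adjusted p was 0.0028 for each of these 3 classes, from the smallest p the 1000 placements can give (two-sided permutation test). Introns held 34.1% against 39.6%, intergenic sequence 15.9% against 27.1%, 5' UTRs 0.417% against 0.778% and noncoding exons 1.05% against 0.812% (adjusted p = 0.0028, 0.0028, 0.00466 and 0.0839, permutation test). The classes add up to the whole and promoters come first, so lower shares of the others follow in part from the promoter share and are not read as depletion. The other classes were therefore compared also among the 2647 summits outside promoters, with placements outside promoters, an alternative added after seeing the data. Introns held 64.8% of these summits (62.9 to 66.6%) against 45.8% at random and noncoding exons 2.00% against 0.941%, while coding exons with 0.529% against 15.9% and 3' UTRs with 1.55% against 5.18% stayed below (adjusted p = 0.0030 for each, permutation test). Intergenic sequence (30.3% against 31.3%, adjusted p = 0.355) and 5' UTRs (0.793% against 0.906%, 0.625, permutation test) did not pass.

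Promoter shares of the top regions were 50.1%, 37.1% and 48.5% in replicates 1, 2 and 3 (45.3% ± 7.07, SD, n = 3). Coding exons took 5.28% of the top regions of replicate 2, 0.318% of those of replicate 1 and 0.238% of those of replicate 3. The promoter share was 3.50 times that of random placements on the arm, 2.37 times that of placements within 10 kb (20.04%) and 3.65 times that of placements matched on GC content (13.004%), the last an alternative added after seeing the data. The coding exon expectation was 18.2% within 10 kb and 5.02% with GC matching. Among summits outside promoters, introns stayed above placements within 10 kb (53.4%) and with GC matching (52.3%), and in the top regions of replicates 1, 2 and 3 held 64.1%, 57.9% and 63.6%. Coding exons held 0.637%, 8.40% and 0.463% of these summits in replicates 1, 2 and 3, against 15.9% at random in each. Intergenic sequence outside promoters lay above placements within 10 kb (25.1%, adjusted p = 0.0030) and below those matched on GC content (33.3%, 0.0024, permutation test). The 5' UTR share outside promoters lay below placements within 10 kb (0.793% against 1.38%, adjusted p = 0.00480) and did not differ from those matched on GC content (0.730%, 0.767, permutation test). The noncoding exon share passed with a TSS distance of 250 bp (1.59%, adjusted p = 0.0200, permutation test) and with GC matching (adjusted p = 0.04995), and lay below the 1.07% of placements within 10 kb.

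**Figure D2:**
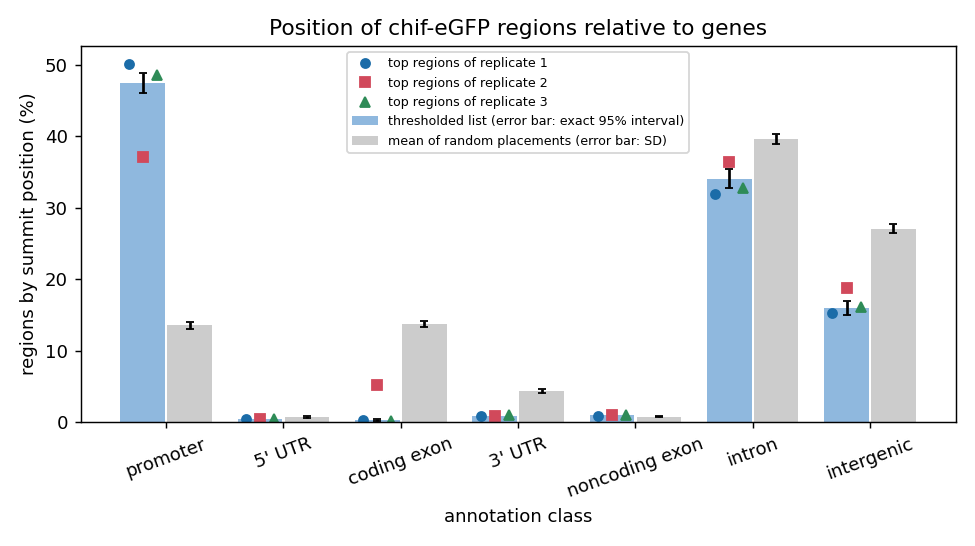
Share of regions by the position of their summit (percent, vertical axis) in each annotation class (horizontal axis), for the thresholded list (blue bars, exact 95% intervals), for 1000 random placements (grey bars, mean and SD) and for the top regions of each replicate (points). Promoters hold 47.4% of the thresholded summits against 13.6% at random, and coding exons 0.278% against 13.7%.

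Promoter summits sat just upstream of the TSS. For the 2245 thresholded summits within 500 bp of a protein-coding TSS, the median position was -96 bp (quartiles -181 and -30 bp), and 1859 of them (82.8%) lay upstream. Medians in the top regions of replicates 1, 2 and 3 were -81, -117 and -86 bp. The median moved to -116 bp without replicate 1 and to -117 bp without replicate 3 or with regions held by all 3 replicates.

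**Figure D3:**
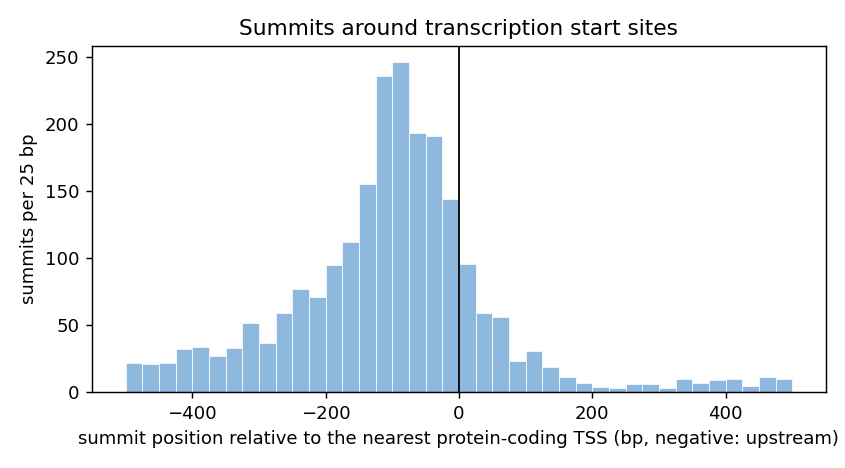
Number of thresholded summits per 25 bp (vertical axis) by their position relative to the nearest protein-coding TSS (horizontal axis, bp, negative values upstream). The histogram peaks upstream of the TSS, where the median of the 2245 summits is -96 bp and 82.8% of them lie.

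Chif-eGFP bound 2879 of 13968 protein-coding genes (20.6%, 19.9 to 21.3%). The top regions of replicates 1, 2 and 3 bound 2947, 2222 and 2923 genes (2697 ± 412, SD, n = 3), and 1637 of the 2879 genes were bound also in each of them. The count was 1597 with the higher-signal part of the list, 1752 without replicate 1, 1676 without replicate 3 and 1584 with regions held by all 3 replicates.

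Bound genes were spread over the large arms, with small differences between them. Genes on 3R were bound more often than the rest (768 of 3421, 22.4% against 20.02%, adjusted p = 0.0166) and genes on 2R less often (534 of 2852, 18.7% against 21.1%, adjusted p = 0.0178, Fisher's exact test, two-sided). None of 23 genes on Y was bound, but the thresholded list held no region on Y at all, so the share there says nothing of binding. The shares were 20.7% on 2L, 21.1% on 3L and 19.9% on X. The small chromosome 4 had 11 of 80 genes bound (13.8%, 7.07 to 23.3%, adjusted p = 0.288, Fisher's exact test), with 16.2%, 2.5% and 17.5% in replicates 1, 2 and 3. Under each other list and TSS distance the odds ratio stayed between 1.11 and 1.17 on 3R (1.16 in the thresholded list) and between 0.815 and 0.926 on 2R (0.862), while the calls did not all hold. The 3R call ended without replicate 1 (13.5% against 12.2% of other genes, adjusted p = 0.107), with the higher-signal part (12.2% against 11.2%, 0.142) and with regions held by all 3 replicates (12.3% against 11.02%, 0.0877, Fisher's exact test). The 2R call ended without replicate 2 (15.2% against 17.01%, adjusted p = 0.0551), at 250 bp (15.2% against 16.9%, 0.0518), with the higher-signal part (10.7% against 11.6%, 0.231) and in 4 lists built here from replicates (0.0761 to 0.250, Fisher's exact test). Chromosome 4 passed wherever replicate 2 had to back a region (2.5% bound against 12.6% of other genes, adjusted p = 0.0118, without replicate 1 and against 12.1%, 0.0174, without replicate 3, Fisher's exact test).

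Genes of the cytoplasmic ribosome, of the cell cycle and of promoter architecture were bound more often than other genes, and genes of smell and taste receptors hardly at all. Chif-eGFP bound 58 of 86 cytoplasmic ribosomal protein genes (67.4%, 56.5 to 77.2%, adjusted p = 9.78e-20), 16 of 30 cell cycle regulators (53.3%, 34.3 to 71.7%, adjusted p = 0.000352) and 11 of 20 architectural and promoter-binding proteins (55%, 31.5 to 76.9%, adjusted p = 0.00256), against 20.3%, 20.5% and 20.6% of the other genes (Fisher's exact test, two-sided). The strongest ribosomal protein regions were at RpS27 (FBgn0039300, 3R:25247386–25247674, signal 696), RpL7 (FBgn0005593, 2L:10200896–10201173, signal 661) and RpS20 (FBgn0019936, 3R:20821885–20822169, signal 637), while RpL10 and RpL10Aa were not bound. Bound cell cycle genes included the checkpoint kinase gene tefu (FBgn0045035, signal 351, from a region 285 bp upstream that it shares with Hsc70-4), Dp (FBgn0011763, signal 336), which encodes the partner of E2F, and the mitotic kinase gene aurA (FBgn0000147, signal 307), while aurB and Bub1 were not bound. Of the architectural group, Chro was followed by Cp190 (FBgn0000283, signal 640), an insulator protein gene, and Nelf-E (FBgn0017430, signal 423), a subunit of the factor that pauses RNA polymerase II, while Clamp and dwg were not bound.

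These 3 calls ended wherever a region had to be backed by replicate 2 together with another replicate. Ribosomal protein genes were bound at 69.8%, 27.9% and 70.9% by the top regions of replicates 1, 2 and 3 (56.2% ± 24.5, SD, n = 3), cell cycle genes at 53.3%, 26.7% and 53.3% (44.4% ± 15.4) and architectural genes at 55%, 40% and 55% (50% ± 8.66). These settings leave fewer bound genes of any kind, so the shares are given with those of other genes, and the odds ratios stood at 8.12, 4.42 and 4.72 in the thresholded list. Without replicate 1 the shares were 20.9%, 20% and 30% against 12.5% of other genes (odds ratios 1.85, 1.75 and 3.00, adjusted p = 0.110, 0.457 and 0.110, Fisher's exact test). Without replicate 3 they were 18.6%, 23.3% and 25% against 11.96 to 11.98% (odds ratios 1.68, 2.24 and 2.45, adjusted p = 0.231 for each, Fisher's exact test). With regions held by all 3 replicates they were 18.6%, 20% and 25% against 11.3% (odds ratios 1.80, 1.96 and 2.61, adjusted p = 0.187, 0.336 and 0.237, Fisher's exact test). Each list thus stayed above other genes in share without passing. Without replicate 2 they were 61.6%, 43.3% and 50% (odds ratios 8.21, 3.85 and 5.03, adjusted p = 9.14e-20, 0.00204 and 0.00204, Fisher's exact test). In the top regions of replicate 2 alone, an alternative added after seeing the data, the ribosomal (adjusted p = 0.0311) and architectural lists (0.0394) passed and the cell cycle list did not (0.293, Fisher's exact test). Among the 7983 genes with no other TSS within 1000 bp, of which 11.9% were bound, the architectural list no longer passed (3 of 6 members, adjusted p = 0.0891, exact test).

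Of 179 chemosensory receptor genes, chif-eGFP bound 1 (0.559%, 0.0141 to 3.07%, adjusted p = 5.84e-16, Fisher's exact test), and the call held under each alternative run. The bound gene was Ir60e (FBgn0035019), with a region at 2R:24531362–24531771 of signal 181 that replicate 2 did not back. Unbound members included Gr10a and Gr10b.

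The lists closest to the known roles of chiffon did not pass against other genes, and their intervals were wide. They ask which genes of these functions had a bound promoter, and so do not test the roles themselves. The exact interval of the bound share was 12.6 to 51.1% for replication licensing and firing (odds ratio 1.59). It was 16.4 to 57.3% for the replication fork and nucleotide supply (2.06) and 12.3 to 45.9% for SAGA and Gcn5 acetyltransferase subunits (1.40). Each interval holds the 20.6% of other genes and also shares well above it. A moderate enrichment of these lists was thus neither shown nor excluded. Of 24 genes of replication licensing and firing, 7 were bound (29.2%, adjusted p = 0.523, Fisher's exact test), among them chif and the replicative helicase genes dpa (FBgn0015929, signal 278) and Mcm2 (FBgn0014861, signal 230), and not Cdc45 or Cdc6. As chif is also the tagged transgene, its place among the 7 is uncertain. Of 23 genes of the replication fork and nucleotide supply, 8 were bound (34.8%, adjusted p = 0.328, Fisher's exact test), with PolD2 (FBgn0027903, signal 427), Top1 (FBgn0004924, signal 350) and RnrS (FBgn0011704, signal 326) the strongest, and not DNAlig1 or Fen1. Of 30 SAGA and Gcn5 acetyltransferase subunits, 8 were bound (26.7%, adjusted p = 0.523, Fisher's exact test), led by Gcn5 itself (FBgn0020388, 3L:12524082–12524332, signal 424), then Ada2b (FBgn0037555, signal 282) and Ada3 (FBgn0030891, signal 225), and not Ada1-1 or Ada1-2. None of the 9 chorion genes, which follicle cells of the ovary amplify, was bound (0%, upper limit 33.6%, adjusted p = 0.438, Fisher's exact test), Cp15 and Cp16 among them. The material was embryos and not ovaries, so this says nothing of amplification. The replication fork list passed with the higher-signal part of the list (30.4%, adjusted p = 0.0414, Fisher's exact test), and licensing genes with no close neighbour were bound in 0 of 5 cases.

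Heat shock, patterning and cell type markers did not pass either. Bound were 7 of 20 heat shock genes (35%, adjusted p = 0.373), 8 of 36 segmentation and homeotic genes (22.2%, 0.836), 5 of 20 neural markers (25%, 0.682), 5 of 20 mesoderm and muscle markers (25%, 0.682), 5 of 16 germ line markers (31.2%, 0.523) and 2 of 14 blood and fat body markers (14.3%, 0.806, Fisher's exact test). Strong single regions lay at the neuronal RNA-binding protein gene elav (FBgn0260400, signal 982), at sls (FBgn0086906, signal 716), which encodes the titin-like protein of muscle, at the anterior determinant gene bcd (FBgn0000166, signal 545) and at Hsp27 (FBgn0001226, signal 508). Others were at Hsc70-4 (signal 351, the region shared with tefu, 166 bp upstream of Hsc70-4), Hsp26 (334), bgcn (290), tin (237), htl (234), piwi (221), ush (196), pros (187), wg (173), zpg (147), oc (146), insc (124) and gcm (114.7). The unbound members named by the rule were CG4456, Hsc70-3, abd-A, Abd-B, ac, ase, Act57B, bap, AGO3, aub, crq and Fbp1.

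The heat shock list passed in the top regions of replicate 1 alone (50%, adjusted p = 0.0109, Fisher's exact test). Against circular shifts of all regions, which ignore where promoters lie and bound 617 genes on average, 8 further lists passed, all but the chorion and the blood and fat body lists. Of the 49 named bound genes, 40 were held by all 3 replicates, and replicate 2 did not back Ir60e, wg, oc, Nelf-E, pros, insc, zpg, ush or gcm. With a TSS distance of 250 bp, mRpS23, tefu, Ada2b, Ir60e, elav and htl were no longer bound, and with 1000 bp the strongest ush region had a signal of 322.

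**Figure D4:**
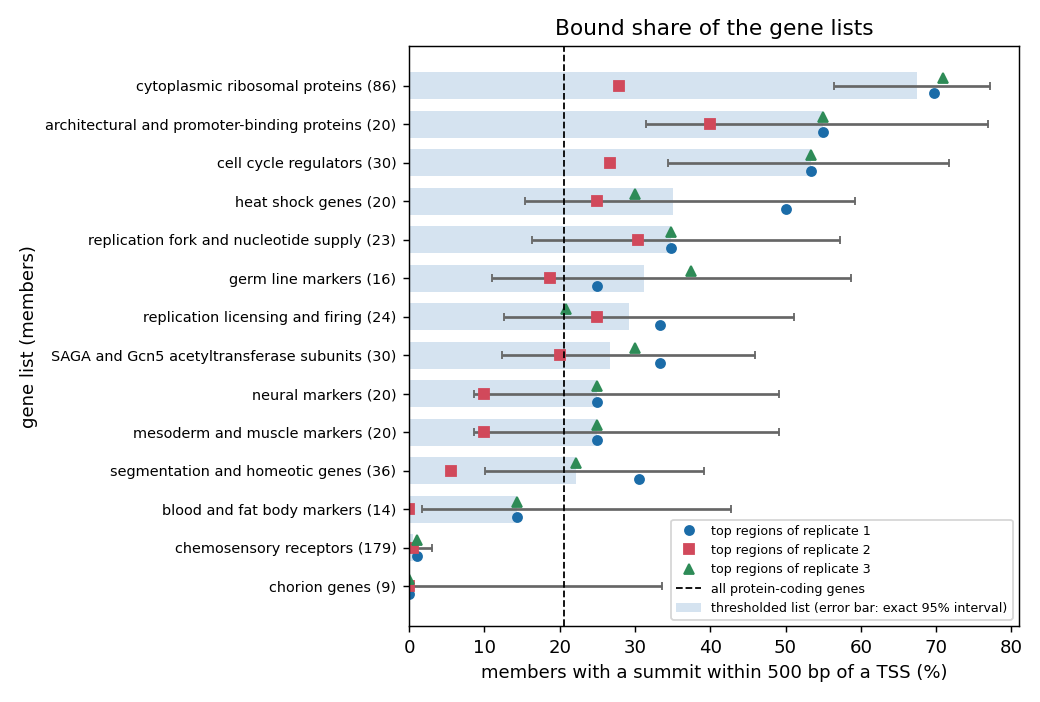
Share of the members of each gene list with a summit within 500 bp of a TSS (percent, horizontal axis), for the thresholded list (bars, exact 95% intervals) and the top regions of each replicate (points), with the share of all protein-coding genes as a dashed line and the number of members in parentheses. Cytoplasmic ribosomal protein genes reach 67.4%, with replicate 2 at 27.9%, and chemosensory receptor genes 0.559%.

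DNA at the bound promoters was richer in A and T than at other TSSs. The windows at 2388 promoter summits had a GC content of 37.3%, against 41.5% at 9913 TSS windows of unbound genes and 44.8% in windows 1000 bp to either side. It was 39.7% where the unbound windows were moved off the TSS by distances drawn from those of the summits, an alternative added after seeing the data. The Inr pattern TCAKTY was found at 41.1% of summits against 52.7% of unbound TSSs (adjusted p = 2.87e-23) and the TATA box pattern STATAAA at 10.1% against 14.8% (adjusted p = 5.49e-09, Fisher's exact test). A run of 8 A was found at 12.1% against 9.84% (adjusted p = 0.00538) and the GAGA motif at 4.48% against 3.36% (adjusted p = 0.0320, Fisher's exact test, two-sided). The unbound windows were centred on TSSs and the summits lay a median of 96 bp upstream, which bears on Inr and the TATA box. At the summits' distances, unbound windows held Inr at 47.8% (adjusted p = 3.56e-08) and the TATA box at 13.6% (adjusted p = 1.64e-05, Fisher's exact test). Against the windows to either side of the same summits both were more frequent at the summit (Inr 36.8% there, adjusted p = 0.000691, and TATA box 7.12%, adjusted p = 4.03e-05, Fisher's exact test).

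Against other TSSs, the outcome for the sites of housekeeping promoters, the DRE (TATCGATA) and motif 1, depended on the windows and on the list. Both were more frequent at bound promoters than in the windows to either side. Windows centred on unbound TSSs held them at 6.85% and 3.36%, also far above the windows to either side. That comparison thus does not separate bound from unbound promoters. The DRE was found at 7.24% of summits and 6.85% of unbound TSSs (adjusted p = 0.542), but at 0.440% of windows to either side (adjusted p = 1.26e-59, Fisher's exact test). Motif 1 was found at 3.02%, 3.36% (adjusted p = 0.524) and 0.209% (adjusted p = 4.09e-24), and the BEAF-32 core CGATA at 39.0%, 37.0% (adjusted p = 0.159) and 22.3% (adjusted p = 5.19e-48, Fisher's exact test). With unbound windows at the summits' distances all 3 were more frequent at summits, as those windows held the DRE at 4.75% (adjusted p = 9.97e-06), motif 1 at 1.78% (0.000624) and CGATA at 32.6% (3.37e-08, Fisher's exact test). Those windows still had a higher GC content than the summits (39.7% against 37.3%), and no motif test was matched on GC content. Against windows centred on unbound TSSs these directions turned with the setting. In the top regions of replicate 2 the DRE (4.97%, adjusted p = 0.00479) and CGATA (32.9%, 0.00170, Fisher's exact test) were less frequent than at unbound TSSs. With 250 bp they were more frequent (8.73%, adjusted p = 0.0140, and 42.0%, 0.000191), as was CGATA in the top regions of replicate 3 (40.3%, 0.0108, Fisher's exact test). Windows of 50 bp gave a lower DRE share at summits than at unbound TSSs (3.35%, adjusted p = 0.00447, Fisher's exact test). Motif 1 was less frequent at summits than at unbound TSSs with windows of 50 bp (1.05%, adjusted p = 3.70e-07), in replicate 2 alone (1.71%, 0.000252) and with the higher-signal part (1.92%, 0.0155, Fisher's exact test). It was so too without replicate 1 (2.13%, adjusted p = 0.0395), with a TSS distance of 1000 bp (2.48%, 0.0400) and with regions held by all 3 replicates (2.11%, 0.0474, Fisher's exact test).

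The GAGA call ended without replicate 1 (4.04%, adjusted p = 0.241, Fisher's exact test), without replicate 3 (4.05%, 0.312), with regions held by all 3 replicates (4.22%, 0.229), with 250 bp (3.85%, 0.446), with the higher-signal part (3.59%, 0.801), in the list built here (4.06%, 0.241), against the windows to either side (3.54% there, odds ratio 1.28, 0.0849) and against unbound windows at the summits' distances (3.65%, odds ratio 1.24, 0.106), where the odds ratio was 1.35 against unbound TSSs, and its direction turned in replicate 2 alone (3.26%). The call of the A run ended with 250 bp (11.3%, adjusted p = 0.102) and in the top regions of replicate 1 (11.2%, 0.109) and of replicate 3 alone (11.3%, 0.0648), and against unbound windows at the summits' distances (10.9% there, odds ratio 1.13 in place of 1.26, 0.124, Fisher's exact test). The other motifs did not pass, and each of them passed or turned under some alternative. Their shares at summits and at unbound TSSs were 0.754% and 1.05% for the Zelda site CAGGTAG, 2.55% and 2.57% for CACGTG, 11.6% and 12.5% for CAGCTG, 3.69% and 4.22% for E2F, 0.419% and 0.161% for CRE (adjusted p = 0.0587, Fisher's exact test) and 77.7% and 78.5% for the DPE-like pattern.

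Of 2080 6-mers, 416 were more frequent and 716 less frequent at promoter summits than at unbound TSSs (1132 past the threshold by Fisher's exact test). With unbound windows at the summits' distances, 331 were more and 495 less frequent. Of the 10 with the smallest p, 8 were made of A and T alone and were more frequent at summits, led by AAAATA (58.1% against 40.1%, adjusted p = 1.63e-53, Fisher's exact test), AAATAT (50.2% against 33.5%) and TTAAAA (48.2% against 31.9%). ACAGTG, with mixed bases, was found at 18.2% of summits against 8.54% of unbound TSSs (adjusted p = 4.80e-36, Fisher's exact test) and 8.44% of windows to either side. AACTGA, whose reverse complement TCAGTT is a form of the Inr pattern, was less frequent (12.3% against 23.03%, adjusted p = 3.06e-31), but not against the windows to either side (11.7%, adjusted p = 0.549, Fisher's exact test).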

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

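The comparison of replicates matched on GC content was the test of this part chosen only after the result was seen. On dm3, the older build, the list of replicate 2 held 718 regions on sequences outside the chromosome arms, against 17 in replicate 1 and 24 in replicate 3. Of the 718, 217 lay on 2RHet, 200 on 3RHet, 192 on 3LHet and 79 on U, and 16 were among the top regions of that replicate. They drew attention because the dm3 lists entered no comparison with genes, and no control library was analysed here. On dm6 the list of replicate 2 held 5499 regions on 2R, 6422 on 3L and 8065 on 3R, against 5203, 6198 and 7840 on these arms of dm3, so the dm6 comparisons cannot be taken as free of such regions.

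Replicate 2 also differed from replicates 1 and 3 on chromosome 4, where its 30000 regions included 28, against 278 and 316. The mean GC content of its regions below the top 5035 was 2.38 points above that of replicate 1 and 3.90 above that of replicate 3, which a library bias towards GC-rich DNA or a different filling of the list under weak enrichment would give, but GC content falls short as the whole cause, because at matched GC content replicates 1 and 3 predicted 244 and 260 regions on chromosome 4, against the 28 listed (exact Poisson interval 18.6 to 40.5). Weak enrichment may contribute and stays open, since summits below the top 5035 of replicate 2 lay in top regions of the others 2.05 times (replicate 1) and 2.19 times (replicate 3) as often as at random, between the bounds set for the test (the random share and 3 times it), against 3.99 and 3.88 times between replicates 1 and 3. Loss of chromosome 4 from the replicate 2 material stays open too, because the 3 regions in its top 1000 against 5 and 6 (intervals 0.619 to 8.74, from 1.63 and from 2.20) made the bound set for that test too weak to exclude it. In the top 5035 replicate 2 had 4 (1.09 to 10.2) against 22 (13.8 to 33.3) and 25 (16.2 to 36.9), with the intervals apart. A loss would give this, but it is the pattern itself over a shorter list. No biological explanation was tested, as the design has 1 group.

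Thresholded regions lay at promoters for 47.4% of summits, which a general recovery of open, highly transcribed DNA might produce. That explanation asks for tRNA genes to be bound more often than protein-coding genes, and 15 of 290 were (5.17%, exact interval 2.92 to 8.39%), against 20.6%. With unique sequence around them the value was 15 of 259 (5.79%). Other small RNA genes, looked at only after the results were seen, went both ways. The snRNA genes were bound in 9 of 32 cases (28.1%, 13.7 to 46.7%), an interval that includes 20.6%. The snoRNA genes were bound in 9 of 269 cases (3.35%, 1.54 to 6.26%). The tRNA share thus speaks for tRNA genes only and does not settle the explanation. Recovery limited to promoters of RNA polymerase II was not tested and stays open, because an untagged library was not analysed here.

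At the chif gene, extra DNA copies of the tagged transgene could raise the whole locus. The pooled list held 5 regions within 10 kb of the middle of chif. Around other protein-coding genes the median was 6, the 95th percentile 13 and the 99th percentile 16, so the number at chif was not raised. The test cannot decide on extra copies, because a count of regions does not measure read depth and the control was not analysed here. A local effect of the transgene at the strongest region was not tested, and neither was binding of chiffon to its own gene.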

How the results depend on the processing

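The tests chosen only after results were seen were the list from replicates 1 and 3, the top regions of single replicates, placements matched on GC content, unbound windows at the summits' distances, summits outside promoters, those of the 4 added gene lists, agreement without a replicate, and alternatives of the median TSS distance and (windows to either side apart) of the 6-mers. Over all results and alternatives, 997 of 1198 values kept their direction and their side of the threshold or stayed within the spread, 58 fell short of the threshold, 44 newly passed, 80 turned in direction and 19 moved. Of the 1198, 304 were signals of named genes at the same thresholded regions, and 300 of these kept. They were counted only where the gene was still bound, so lost genes do not appear. Another 150 belonged to the named 6-mers, picked for the smallest p in these data, and 149 kept. The total is thus largely set by construction and is no measure of stability. Agreement between replicates, as a mean and by pair, kept its side in all 23 values, with means of 54.3% (10000 top regions) to 79.6% (without replicate 2), and the promoter call in each of its 14, with shares of 37.1% (replicate 2 alone) to 57.7% (1000 bp). Chemosensory receptor genes stayed under-bound throughout. Where an alternative asks for more replicates or higher signal, fewer regions are left by construction. Otherwise the cause was not tested. Shorter lists bind fewer of the other genes too, 11.3% of them with regions held by all 3 replicates, so a lower share is not by itself a lower odds ratio. Y held no thresholded region, and its values say nothing of binding. Most turned directions were of values past the threshold in neither setting. The depth of the libraries is unknown, so what it limits could not be measured. No paired analysis was possible because the labels give 1 group. The dm3 lists were used for region counts and agreement only, as no dm3 annotation was used here.

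With the higher-signal part of the list, 2517 regions and 1597 bound genes were left and 0 arms passed, with shares of 10.7% for 2R (adjusted p = 0.231), 12.2% for 3R (0.142) and 0% for Y (0.142, Fisher's exact test). The replication fork list passed at 30.4% (0.0414), and segmentation genes (2.78%), neural markers (10%), the DRE (6.15%), the BEAF-32 core (36.3%) and the DPE-like pattern (78.6%) turned.

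With a TSS distance of 250 bp, noncoding exons passed at 1.59%, 1 arm passed, and 2R (15.2%) and Y (0%) did not (adjusted p = 0.0518 each, Fisher's exact test). Neural and muscle markers (15% each), motif 1 (3.69%), CACGTG (2.81%) and CAGCTG (12.9%) turned. With 1000 bp, 2L (23.5%), segmentation genes (22.2%), the DRE (6.03%), the BEAF-32 core (35.7%) and CACGTG (2.62%) turned.

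Leaving out 1 replicate gave the following ranges, each from lowest to highest. Bound genes numbered 1676 (without replicate 3) to 2324 (without replicate 2), and passing arms 1 (without replicate 2) to 3 (without replicate 3). Bound shares were 10.4% (without 3) to 15.2% (without 2) on 2R, 13.3% (without 3) to 18.2% (without 2) on 3R, 2.5% to 11.2% on chromosome 4 and 0% throughout on Y. Cytoplasmic ribosomal protein genes ranged from 18.6% (without 3) to 61.6% (without 2), cell cycle genes from 20% (without 1) to 43.3% (without 2), architectural genes from 25% (without 3) to 50% (without 2), segmentation genes from 2.78% to 13.9%, neural markers from 10% to 20% and germ line markers from 12.5% to 25%. The DRE ranged from 5.60% to 7.40%, the BEAF-32 core from 34.7% to 38.8% and CACGTG from 2.48% to 2.70%.

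With regions held by all 3 replicates, 1584 genes were bound. The 3R (12.3%, adjusted p = 0.0877), Y (0%, 0.142), ribosomal (18.6%, 0.187), cell cycle (20%, 0.336) and architectural calls (25%, 0.237) ended, and chromosome 4 passed (2.5%, 0.0254, Fisher's exact test). Segmentation genes (2.78%), neural markers (10%), the DRE (5.63%), the BEAF-32 core (34.8%) and CACGTG (2.58%) turned. In the list built here from backed top regions, the 2R call ended (17.7%, 0.0761), and 2L (18.9%) and CACGTG (2.76%) turned.

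In the list from replicates 1 and 3, 1 arm passed, the 2R (15.9%, adjusted p = 0.0956) and Y calls (0%, 0.0569, Fisher's exact test) ended, and 2L (17.0%), CACGTG (2.98%), CAGCTG (12.6%) and E2F (4.34%) turned. In replicate 1 alone, the 2R call ended (20.1%, 0.250), heat shock genes passed (50%, 0.0109), and proteasome subunits (25%), 2L (20.5%), CACGTG (2.77%), CAGCTG (13.1%) and E2F (4.72%) turned. In replicate 3 alone, the 2R call ended (19.9%, 0.224), the BEAF-32 core passed (40.3%, 0.0108, Fisher's exact test), and 2L (20.8%), licensing genes (20.8%), CACGTG (2.70%) and CAGCTG (13.1%) turned. In replicate 2 alone, chromosome 4 passed (2.5%, 0.00129), the Y (0%, 0.0695) and cell cycle calls (26.7%, 0.293) ended, and 8 motifs passed. There 2L (15.2%), X (16.0%), segmentation genes (5.56%), neural and muscle markers (10% each), the DRE (4.97%), the BEAF-32 core (32.9%) and GAGA (3.26%) turned.

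Against windows 1000 bp to either side, 8 motifs passed, and motif 1 (3.02%), the TATA box (10.1%), CAGCTG (11.6%), E2F (3.69%), Inr (41.1%) and AACTGA (12.3%) turned. With windows of 50 bp, 9 motifs passed, and the DRE (3.35%) and the BEAF-32 core (22.2%) turned. With unbound windows at the summits' distances, motif 1 (3.02%), CACGTG (2.55%) and CAGCTG (11.6%) turned. With placements within 10 kb, noncoding exons turned (1.05%) and the intergenic call ended (15.9%), and with placements matched on GC content noncoding exons passed (1.05%). Among summits outside promoters, where shares no longer depend on the promoter share, introns turned to above random (64.8%) and noncoding exons passed (2.00%) with each of the 3 kinds of placement. The intergenic call ended on whole arms (30.3%) and turned within 10 kb (30.3%). The 5' UTR call ended on whole arms (0.793%), held within 10 kb (0.793%) and turned with GC matching (0.793%). In the top regions of replicates 1, 2 and 3 introns turned (64.1%, 57.9% and 63.6%), noncoding exons passed (1.87%, 1.61% and 1.93%), the intergenic call ended (30.7%, 29.9% and 31.2%), and the 5' UTR call turned in 1 and 3 (0.955% and 0.926%) and ended in 2 (0.790%).

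Against circular shifts, licensing (29.2%), replication fork (34.8%), SAGA (26.7%), segmentation (22.2%), heat shock (35%), neural (25%), muscle (25%) and germ line lists (31.2%) passed, with adjusted p of 0.0040 to 0.0233 (permutation test), and blood and fat body markers turned (14.3%). Among genes without a close neighbouring TSS, the architectural call ended (50%, adjusted p = 0.0891, Fisher's exact test), and licensing genes (0%) and blood and fat body markers (18.2%) turned.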

Other observations

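The further gene lists, the shares of small RNA genes and the 8-base test of this part were chosen only after the report's results were seen. Mitochondrial ribosomal protein genes were added because mRpS10 and mRpS23 stood at the strongest regions, so these members are not independent evidence. Chif-eGFP bound 33 of 73 of them (45.2%, exact interval 33.5 to 57.3%, adjusted p = 1.13e-05 over the 4 added lists, Fisher's exact test, two-sided), with 41.1%, 27.4% and 41.1% in the top regions of replicates 1, 2 and 3. Polycomb group genes were added because of ph-p, which is likewise not independent evidence, and were bound in 9 of 18 cases (50%, 26.0 to 74.0%, adjusted p = 0.0105, Fisher's exact test), with 55.6%, 33.3% and 61.1% in replicates 1, 2 and 3. The bound members were ph-p, ph-d, Pc, Psc, E(z), Su(z)12, Su(z)2, Sfmbt and Jarid2, which include subunits of both Polycomb repressive complexes. Without the members that led to the choice, 31 of 71 mitochondrial ribosomal protein genes (43.7%, adjusted p = 4.31e-05) and 8 of 17 Polycomb group genes (47.1%, adjusted p = 0.0262, Fisher's exact test) were bound. Both calls ended in 5 settings that bind fewer genes of any kind, so odds ratios are given, which were 3.20 and 3.86 in the thresholded list. They were 1.97 and 2.69 without replicate 1 (adjusted p = 0.0835 and 0.131), 1.45 and 2.83 without replicate 3 (0.480 and 0.223) and 1.24 and 3.01 with regions held by all 3 replicates (0.476 and 0.181, Fisher's exact test). With the higher-signal part they were 1.85 and 2.22 (adjusted p = 0.172 and 0.284) and in replicate 2 alone 2.00 and 2.65 (0.0586 and 0.107, Fisher's exact test). The calls held without replicate 2 (2.17 and 5.03, adjusted p = 0.00798 and 0.00443, Fisher's exact test). Proteasome subunits (8 of 44, 18.2%, adjusted p = 0.852) and aminoacyl-tRNA synthetases (9 of 32, 28.1%, adjusted p = 0.371, Fisher's exact test) did not pass. Among small RNA genes, 9 of 32 snRNA genes (28.1%, 13.7 to 46.7%) and 9 of 269 snoRNA genes (3.35%, 1.54 to 6.26%) were bound.

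The 2647 regions away from promoters may hold a recurring sequence. Of 5845 8-mers, the one with the smallest p on 2L and 3L was CACTGAGA, at 84 of 1075 summits (7.81%) against 0.558% of windows 1000 bp to either side. On the other arms, which had no part in the choice, it was found at 100 of 1572 summits (6.36%, exact interval 5.21 to 7.68%) against 0.541% (p = 4.18e-32, Fisher's exact test, two-sided). It was found at 6.21%, 5.91% and 6.48% of the top regions away from promoters in replicates 1, 2 and 3, and at 1.76% of promoter summits against 0.314% of the windows beside them. As a hypothesis, a factor that reads this sequence could lie with chif-eGFP at part of the regions away from promoters. The test does not show which factor that is, and the arms share the same libraries and the same control.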
